A study of Aspergillus nidulans with 4 samples.

How the data were processed

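The series compared RNA of an Aspergillus nidulans strain without the mitogen-activated protein kinase gene mpkA (strain AN1404) with RNA of its parental strain (AN1405), with 2 libraries per strain. Per the labels' protocols, mycelium was grown in rich, low-pH medium and harvested in late exponential phase, RNA was isolated with Trizol, and libraries were made with the TruSeq RNA kit, version 2, which does not mark the strand. The series text speaks of biological and of technical replicates without saying which libraries are which. The p-values therefore measure the spread between these libraries, which may be technical only.

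Per the submitters' processing notes, the tools were Bowtie2, HTSeq and DESeq. Their versions, the genome build and the counting options are not given in the sources used here. The authors deposited 3 tables of 10930 rows, of which 10721 have gene identifiers beginning with AN and 209 are RNA genes. The signal values in the authors' deposited tables are means over 2 libraries of reads per gene, each divided by a size factor. The ratio, or fold change, in the authors' deposited 2-strain table is parental over deletion strain, and its sign was turned here so that positive log2 values mean higher in the deletion strain. The p-values and q-values in that table are the authors', per the file headers, and a q-value printed here as 0 was listed as 0 because it was too small for the table. The tables carry start and stop positions in bp without chromosome names. The columns of the 2-strain table were assigned to strains from the strain names that the tables carry. The means of a strain in its own table and in the 2-strain table were proportional across genes, with a ratio of 0.939 (SD 1.9e-05) for the parental strain and 1.04 (SD 3.2e-05) for the deletion strain. In the other tables, 2 columns belong to no sample of this series and were not used.

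The design, the gene lists, the rule for named genes and the alternatives not said to be added were fixed before the data were examined. That design assumed that the files could hold counts per library, but they held means. The main result is therefore the authors' deposited comparison, the choice the design named for that case, called at a q-value under 0.05. Each strain's mean stands in 2 tables with different size factors, which gives 2 equations per gene, and these were solved for whole reads in both libraries. Whole reads were recovered for 100% of the 10930 genes in each strain, within a tolerance of 0.25 reads, with a largest deviation of 0.156 reads in the parental and 0.101 reads in the deletion strain. None of the solutions was negative, 0 in each strain, and size factors recomputed from the recovered reads equalled those of the tables. In a simulation of 10930 genes per strain, 100% of the values were recovered exactly. The recovered libraries are called a and b and carry no replicate number. They held 34871842 and 33027324 reads on genes for the parental strain and 31674270 and 31609185 for the deletion strain. The 10 most abundant genes took 5.71% and 5.65% of the parental and 6.08% and 6.08% of the deletion reads.

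The recovered reads entered a test chosen after seeing the data, the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment. The standard error (SE) of a log2 change was taken as the change divided by the square root of the F statistic. For large changes with few reads in 1 strain this value falls below counting error, so it is not printed for such genes. Alternatives on the recovered reads were DESeq2 1.42.0, limma 3.58.1 with a trend on log2 values with a prior count of 2, DESeq2 size factors, library totals, no filter, leaving out each library, a replicate block, a coefficient of variation set to 0.1 or 0.2, and removal of a gene length trend. When 200 of 9338 genes were changed in data simulated for the comparison of the deletion with the parental strain, edgeR recovered 80% of those changed 1.5-fold and 98% of those changed 3-fold, and called 0.0553% of the unchanged genes. The simulation gave every gene the same spread, estimated from these libraries, and raised as many genes as it lowered. Its rate of false calls holds for such data only and does not carry over to the calls made here. Where a strain had 0 reads, a fold change is a lower bound computed against 3 reads over its 2 libraries. Where it had 1 to 3 reads, the ratio has an exact 95% interval from the binomial distribution. Intervals and bounds cover counting error only.

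The 27 gene lists were made from identifiers and from words in the annotation text of the files. One identifier of the sterigmatocystin cluster, AN7813, was not analysed here, and AN4384 was dropped because its text names a folate gene. Lists were tested with cameraPR of limma, on the ranks of the authors' signed statistic with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. P-values under 1e-300 tied. Alternatives were camera on recovered reads with the preset and with an estimated correlation, and fry. The estimated correlation rests on 4 libraries, and with it none of the 27 lists had an adjusted p under 0.70. A call lost under that setting therefore does not set 1 list apart from the others. Words can match inside other words or in the text of other processes. Lists without such members were added after seeing the data for cell cycle, septation, autophagy, chitin synthases, chaperones and glycolysis, and the 10 added lists were adjusted together. Other lists kept members of that kind, such as AN7041, a signalling mucin matched by the word cellulase. The list of chitinases and glucanases kept several beta-1,4-endoglucanases, such as AN6786, matched by the word glucanase inside endoglucanase. It was not tested without them.

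The rule for named genes took mpkA, the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap and whose mean reached 50 normalized reads in the higher strain, up to 4 called members of each list by size of change, and marker and reference genes. A change from or to 0 reads ranked as the largest. Of the 117 genes the rule selected, the text names those needed to describe each group. Gene names came from the fixed lists and from the RefSeq table of assembly ASM1142v1, in which 9974 identifiers had a match and 779 a symbol. That table was also used for which genes neighbour each other, and none of its coordinates are printed. Chitin synthase names differ between sources, so these genes are given by identifier and class. The search for runs of neighbouring genes was tried on simulated data of 8776 genes for this comparison, in which 3 of 3 planted runs and 0 others were found. The simulated background was held below the change required of a run member, and planted genes were set above it. That outcome was therefore fixed in advance, and it gives no rate of false runs in the deposited data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.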

Results

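RNA was compared between an Aspergillus nidulans strain lacking mpkA, which encodes the mitogen-activated protein kinase of the cell wall integrity pathway, and its parental strain. The purpose given by the submitters was to look for unknown functions of the kinase in cultures without added stress. There were 2 libraries per strain, with 34871842 and 33027324 reads on genes in the parental strain and 31674270 and 31609185 in the deletion strain. Values are the authors' means of normalized reads over the 2 libraries of a strain, and reads per library are those recovered from these means.

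The deleted gene, mpkA (AN5666, positions 2038483 to 2039780 on the plus strand in the files, which name no chromosome), had 6 and 3 reads in the deletion libraries and 6993 and 6437 reads in the parental libraries. In the authors' deposited table its mean was 5.01 against 6013 normalized reads, a 1199-fold difference (q = 0). The log2 change from edgeR on the recovered reads was -10.21 with a standard error of 0.09. Its 3' end overlaps AN5665 on the opposite strand between positions 2039721 and 2039780, and reads within that stretch belong to either gene when the strand is not known.

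The 2 libraries of a strain lay close together. The median absolute log2 difference between them was 0.0504 over 9313 genes in the parental strain and 0.057 over 8917 genes in the deletion strain, among genes with at least 20 reads. Within 1.2-fold lay 92.0% of these genes in the parental and 90.1% in the deletion strain. The correlation of log2 values across genes, which are not independent replicates, was 0.998 and 0.997. Chi-square per degree of freedom, taken from the median gene, was 1.54 and 1.68, so the libraries of each strain differed by more than repeated draws of reads.

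Most genes tested were called in the main comparison. Of 10505 genes tested in the authors' deposited table, 7585 (72.2%) passed a q-value of 0.05, with 3810 higher and 3775 lower in the deletion strain. Changes of at least 2-fold went mainly downward, with 1904 genes lower and 958 higher in the authors' deposited table. With edgeR's quasi-likelihood test on the recovered reads and Benjamini-Hochberg adjustment, 8075 of 9338 genes were called, 7527 of them also called by the authors. With a coefficient of variation assumed at 0.2, chosen after seeing the data, 4095 of the 9338 (43.9%) were called. Scaling by library totals in edgeR moved the median log2 change of all genes from -0.02 to -0.21. It moved the split of called genes from 3966 higher and 4109 lower to 3066 higher and 4997 lower, so directions of small changes are relative to the scaling. Among called changes of at least 2-fold, it moved the split from 938 higher and 1942 lower to 707 higher and 2296 lower. With 2 libraries against 2, a permutation test could not go below p = 0.333.

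**Figure D1:**
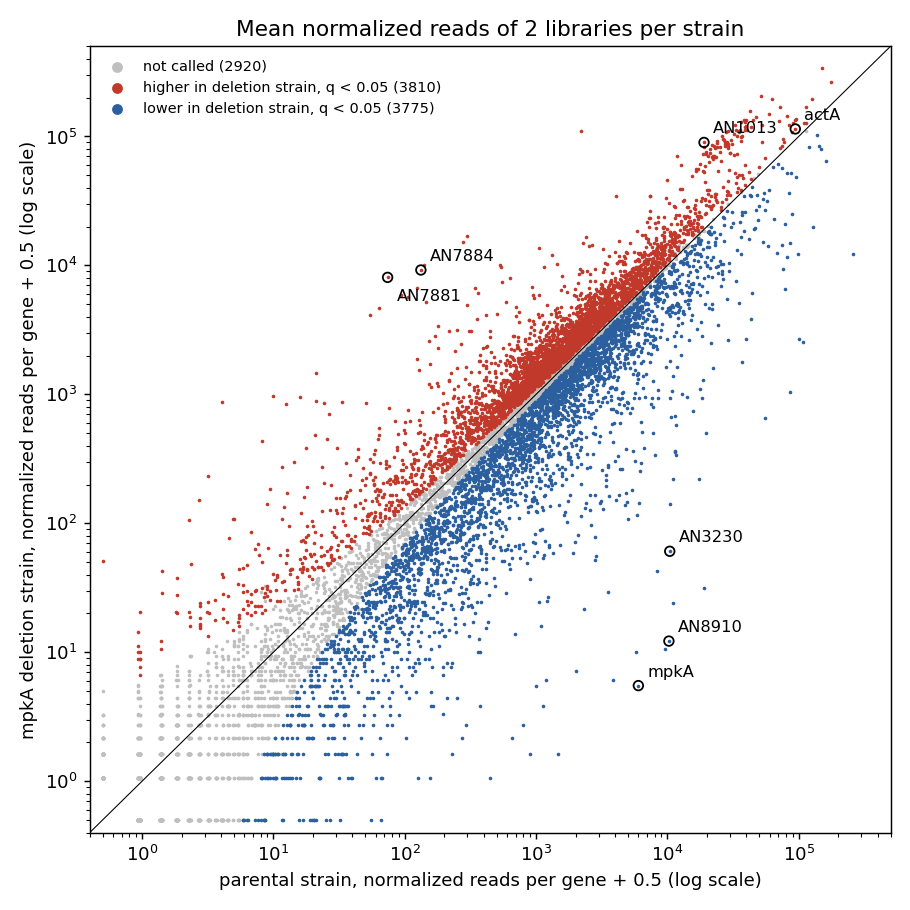
Mean normalized reads of each tested gene in the parental strain (x axis) and the mpkA deletion strain (y axis), both on log axes with 0.5 added; each point is 1 gene, and the line marks equal values. Genes called higher (3810) and lower (3775) lie on both sides of the line, with mpkA, AN3230 and AN8910 far below it and AN7881 and AN7884 far above it.

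The largest falls included genes of secondary metabolism. In the authors' deposited table, the polyketide synthase gene AN8910 had 11.7 normalized reads against 10272 in the parental strain, an 877-fold difference (q = 0). AN3228, a predicted prenyltransferase, was 696-fold lower (q = 0) in the authors' deposited table, and AN8928, an ABC transporter, was 948-fold lower (q = 0). The predicted monooxygenase AN3227 had 2 reads in 1 deletion library and 0 in the other against 1724 and 1580, a ratio of 1323 (95% interval 367 to 10962) in the authors' deposited table. The phosphatidylserine decarboxylase gene AN7385 had 0 and 2 reads against 1000 and 1022, a ratio of 811 (95% interval 225 to 6710). AN6788, a putative transcription factor, was 613-fold lower in the authors' deposited table (q = 0). AN5171, of unknown function, and AN9441, annotated for carnitine and choline transport, had 0 reads in both deletion libraries, and were at least 39.1-fold and 32.9-fold lower. They ranked among the 10 largest falls because a fall to 0 reads counted as unbounded. Genes outside the 10, such as AN3229 (472-fold), fell by more than these bounds. AN5424, annotated only by orthologs, had 1 and 0 reads against 512 and 489, a ratio of 806 (95% interval 144 to 31790), and mpkA itself was among the 10 largest falls. For AN8910, AN3228, AN8928, AN3227, AN7385, AN6788 and AN5424, the 95% interval of the share of reads left overlapped that of the deleted mpkA, which kept 0.0834% of its parental level. On the recovered reads edgeR gave a log2 change of -9.78 for AN8910 and -9.89 for AN8928. The share of reads left was 0.114% (95% interval 0.0706 to 0.174%) for AN8910 and 0.105% (95% interval 0.0625 to 0.167%) for AN8928.

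The largest rises centred on genes next to each other. AN7881, a putative cytochrome P450, rose 110-fold (q = 0) in the authors' deposited table, from 73.6 to 8075 normalized reads. The nonribosomal peptide synthetase gene AN7884 rose 69.6-fold (q = 2.66e-267) in the authors' deposited table. Within the same neighbourhood, the authors' deposited table gave rises of 102-fold for the transporter AN11031, 76.0-fold for the oxidoreductase AN11028, 74.4-fold for AN7883 and 72.0-fold for the aminotransferase AN7876. Outside it, the transmembrane transport gene AN2783 rose 245-fold (q = 3.03e-175), AN5427, a predicted chromate transporter, 87.9-fold, and AN2559, with oxidoreductase and transferase domains, 71.4-fold in the authors' deposited table. AN9219, another transmembrane transport gene, had 50 and 40 reads against 0 and 0, at least 37.3-fold higher. On the recovered reads edgeR gave a log2 change of 6.75 for AN7881 and 7.85 for AN2783. The parental libraries held 97 and 68 reads of AN7881 and only 6 and 2 of AN2783.

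Ribosomal protein genes rose together. All 17 members tested were called higher, 17 also when adjusted over the list alone, with 0 lower, and 14 rose at least 2-fold in the authors' deposited table. AN1013, for 60S protein L5, rose 4.73-fold (q = 0), AN3413, for an S2 and S5 homologue, 3.83-fold, AN4802, for L21, 3.82-fold and AN4087, for a 40S protein, 3.75-fold in the authors' deposited table. On the recovered reads edgeR gave a log2 change of 2.22 (SE 0.03) for AN1013. Under library totals 17 members were higher as well. The median log2 change was 1.80, and the list test gave an adjusted p of 1.31e-08. With an estimated correlation the call was lost (adjusted p = 0.70), a setting under which no list was called. The list rests on the phrase ribosomal protein in the annotation. A second phrase, structural constituent of ribosome, with mitochondrial members left out, was chosen after seeing the data. It gave 34 of 34 genes called higher, with a median log2 change of 1.59 (adjusted p = 4.31e-15 over the 10 added lists).

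Genes of mitochondrial respiration were mostly higher as well. Of 55 members tested, 46 were called higher, 2 lower and 7 not called, with the same counts adjusted over the list alone (46 and 2). The list test gave an adjusted p of 5.63e-07 and a median log2 change of 0.52, and the call was lost with an estimated correlation (adjusted p = 0.70). The largest rises were of genes encoded in the mitochondrion. In the authors' deposited table, the NADH dehydrogenase subunit 4L gene AN20000 rose 10.4-fold (q = 1.90e-08) and the subunit 3 gene AN20018 6.09-fold (q = 9.13e-06). The cytochrome c oxidase subunit II gene AN20019 rose 5.35-fold and the ATP synthase subunit 6 gene AN20010 5.10-fold in the authors' deposited table. AN20000 rested on 33 and 35 reads against 2 and 6, and AN20019 on 133 and 88 against 19 and 32. Whether these few reads measure expression of the mitochondrial genes, rather than how the libraries took them up, was not tested. Split by genome after seeing the data, 35 of 42 nuclear members were higher with a median log2 change of 0.44 (adjusted p = 4.41e-07 over the 10 added lists), and 11 of 13 mitochondrial members with a median of 2.27 (adjusted p = 0.056). Transcripts of the 28 mitochondrial identifiers made up 0.081% and 0.0586% of reads in the deletion libraries and 0.036% and 0.0434% in the parental libraries.

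Secondary metabolite backbone enzymes, the synthases that begin polyketide and nonribosomal peptide pathways, fell more often than they rose. Of 54 members tested, 27 were called lower, 3 higher and 24 not called, with 26 lower and 3 higher adjusted over the list alone. Besides AN8910 and AN7884, the polyketide synthase AN3230 fell 173-fold (q = 0) and orsA (AN7909), the polyketide synthase of orsellinic acid, 31.1-fold (q = 6.95e-41) in the authors' deposited table. The list test gave an adjusted p of 0.00824, lost with an estimated correlation (adjusted p = 0.70). In the orsellinic acid cluster all 5 members were called lower, 5 also adjusted over the list alone, with orsC 14.8-fold, orsE 8.02-fold and orsB 4.34-fold lower in the authors' deposited table. Only 4 of the 5 fell at least 2-fold, and the exception was orsD. In the penicillin cluster all 3 genes fell, 3 also adjusted over the list alone. The acyltransferase gene aatA was 2.79-fold lower, the synthetase gene acvA 1.85-fold and ipnA 1.58-fold in the authors' deposited table. The list tests had an adjusted p of 0.102 for orsellinic acid and 0.102 for penicillin. Without deletion library b the orsellinic acid list was called (adjusted p = 0.0497, in a range of 0.0497 to 0.70 over the camera alternatives). In the sterigmatocystin cluster, 2 of 17 genes tested were lower, 1 higher and 14 not called (2 and 1 adjusted over the list alone; list adjusted p = 0.649). In edgeR, which tested 10 of them, 4 were lower and 1 higher, and library totals moved these to 7 and 1. AN7805, a norsolorinic acid reductase, had 0 and 0 reads against 15 and 21, at least 9.64-fold lower.

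Most sugar transport genes were lower, in a list test that hung on the settings. Of 11 members, 9 were called lower, 1 higher and 1 not called, with 9 and 1 adjusted over the list alone. AN6669, a high-affinity glucose transporter, fell 24.3-fold (q = 0) and AN4590, a sugar transporter, 15.0-fold (q = 2.31e-68) in the authors' deposited table. AN3199 had 0 and 1 reads against 29 and 21, a ratio of 39.9 (95% interval 6.89 to 1618). The list test gave an adjusted p of 0.0478. The call was lost with an estimated correlation (adjusted p = 0.712), under library totals (adjusted p = 0.147), and without parental library a (adjusted p = 0.0556) or b (adjusted p = 0.0509), in a range of 0.0132 to 0.712 over the camera alternatives.

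Chaperone and heat shock genes passed the list test narrowly, with an adjusted p of 0.0478. Of 34 members, 21 were called higher, 7 lower and 6 not called (21 and 7 adjusted over the list alone). The endoplasmic reticulum chaperone bipA rose 2.58-fold (q = 0), AN4863, whose orthologs carry copper to respiratory complex IV, 2.45-fold, AN12105, a chaperone-binding gene, 2.40-fold and tim44, of mitochondrial import, 2.30-fold in the authors' deposited table. The call was lost on recovered reads (adjusted p = 0.0934), with DESeq2 size factors (adjusted p = 0.0813), with an estimated correlation (adjusted p = 0.70) and without any 1 library (adjusted p = 0.075 to 0.123). It was also lost under library totals (adjusted p = 0.305), where edgeR had 15 members higher and 15 lower in place of 21 and 8, in a range of 0.075 to 0.70 over the camera alternatives. Without 5 metal chaperones, left out after seeing the data, 17 of 29 were higher and 7 lower, and the call was lost as well (adjusted p = 0.0846 over the 10 added lists).

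No cell wall list was called. In the cell wall integrity pathway, 3 of 8 members were higher, 3 lower including mpkA, and 2 not called, with 3 and 3 adjusted over the list alone (list adjusted p = 0.816). Without mpkA, left out after seeing the data, 3 of 7 were higher and 2 lower, and the direction of the list test turned from lower to higher (adjusted p = 0.822 over the 10 added lists). In edgeR, library totals moved the 8 members from 3 higher and 3 lower to 2 and 5. The sensor gene wscB rose 1.74-fold (q = 3.96e-77), wscA fell 1.71-fold (q = 1.19e-91), and the kinase kinase gene mkkA rose 1.29-fold in the authors' deposited table. The chitin synthase list of 12 had 5 lower, 2 higher and 5 not called (5 and 2 adjusted over the list alone; list adjusted p = 0.308). The 2 higher genes, AN3445 and AN8765, are annotated for regulation of chitin synthase activity. Without the 3 members of that annotation, left out after seeing the data, 5 of 9 were lower, 0 higher and 4 not called (adjusted p = 0.0592 over the 10 added lists). AN4367, a putative chitin synthase III, fell 7.27-fold (q = 6.93e-22), the class II gene AN7032 1.74-fold and the class VI gene AN6317 1.56-fold in the authors' deposited table. For glucan synthesis, 3 of 5 members were higher, 1 lower and 1 not called (3 and 1 adjusted over the list alone; list adjusted p = 0.497). The 1,3-beta-glucan synthase gene fksA rose 1.32-fold and the alpha-1,3-glucan synthase gene agsA fell 2.69-fold, from 193 to 71.9 normalized reads, in the authors' deposited table. The gene not called was agsB, annotated for the major alpha-1,3-glucan synthase complex, with 10421 against 10943 normalized reads (q = 0.0723). Chitinases and glucanases had 22 lower, 12 higher and 15 not called of 49 (22 and 12 adjusted over the list alone; list adjusted p = 0.60), with the chitinase AN11059 13.8-fold and the endoglucanase AN6786 17.5-fold lower in the authors' deposited table. AN11059 rested on 4 and 4 reads against 73 and 65. AN6786 is annotated as a beta-1,4-endoglucanase and also stood in the plant polysaccharide list. The more abundant chitinase genes chiB and chiA rose 3.33-fold (q = 0) and 1.94-fold (q = 6.25e-159), to 11872 and 18214 normalized reads.

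Developmental regulators differed gene by gene. Of 15 conidiation genes, which also mark conidial cells among hyphae, 9 were lower, 3 higher and 3 not called (9 and 3 adjusted over the list alone; list adjusted p = 0.274). The regulator abaA fell 9.02-fold (q = 8.16e-179) and the hydrophobin rodA 4.91-fold, while fluG rose 5.66-fold (q = 0) and the spore laccase yA 4.26-fold in the authors' deposited table. Of 8 sexual development genes, 5 were lower, 1 higher and 2 not called (5 and 1 adjusted over the list alone; list adjusted p = 0.119). The factor nosA fell 6.50-fold, veA 2.65-fold, laeA 1.57-fold and nsdD 1.54-fold in the authors' deposited table.

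Metabolic and transport lists were mixed. Among 80 plant polysaccharide degradation genes, 34 were lower, 8 higher and 38 not called (33 and 8 adjusted over the list alone; list adjusted p = 0.102). The pectinesterase gene pmeA had 0 and 0 reads against 26 and 33, at least 15.8-fold lower. On recovered reads that list was called (adjusted p = 0.00167), as was cytochrome P450 (adjusted p = 0.0311), in which 40 of 101 were lower, 17 higher and 44 not called (40 and 17 adjusted over the list alone; main adjusted p = 0.102). The P450 gene AN3225 fell 42.9-fold in the authors' deposited table. With an estimated correlation neither was called (adjusted p = 0.70 each), nor was cytochrome P450 under library totals (adjusted p = 0.122). The ranges over the camera alternatives were 9.37e-04 to 0.70 for plant polysaccharides and 0.0132 to 0.70 for cytochrome P450. For glycolysis and fermentation, 18 of 39 were lower, 14 higher and 7 not called, with 19 and 14 adjusted over the list alone (list adjusted p = 0.684). Without 7 aldolases of other pathways, left out after seeing the data, 16 of 32 were lower and 12 higher (adjusted p = 0.766 over the 10 added lists). The alcohol dehydrogenase III gene AN2286 fell 31.7-fold (q = 0) and the pyruvate decarboxylase gene AN4888 14.3-fold (q = 0) in the authors' deposited table. Amino acid transport had 5 of 8 higher, 2 lower and 1 not called (5 and 2 adjusted over the list alone; list adjusted p = 0.308), with the permease AN2781 rising 9.16-fold in the authors' deposited table. Nitrate assimilation had 1 higher, niaD by 2.25-fold, and 2 lower, nirA by 2.56-fold and areA by 1.51-fold, of 5 in the authors' deposited table (1 and 2 adjusted over the list alone; list adjusted p = 0.601). In edgeR, library totals moved these 5 from 1 higher and 2 lower to 1 and 4.

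Stress and iron genes also went both ways. Of 27 oxidative stress genes, 12 were higher, 11 lower and 4 not called (12 and 11 adjusted over the list alone; list adjusted p = 0.42). The hyphal catalase catB rose 3.55-fold and the superoxide dismutase AN0785 6.56-fold, while the thioredoxin reductase AN8218 fell 79.7-fold (q = 0) in the authors' deposited table. Of 18 siderophore and iron genes, 10 were lower, 5 higher and 3 not called (10 and 5 adjusted over the list alone; list adjusted p = 0.60). The ornithine monooxygenase sidA rose 3.68-fold and the transporter mirA fell 3.16-fold in the authors' deposited table. Of 10 other kinase and two-component signalling genes, 4 were higher, 3 lower and 3 not called (4 and 3 adjusted over the list alone; list adjusted p = 0.60), and in edgeR library totals moved them from 4 higher and 3 lower to 3 and 5. The kinase genes pbsB and sakA rose 1.64-fold and 1.59-fold in the authors' deposited table.

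Growth-related lists showed no call. Septation and polarity had 21 of 40 higher, 12 lower and 7 not called, with 22 and 12 adjusted over the list alone (list adjusted p = 0.344). Its largest changes were of genes matched by the word forming, such as afeA, an adenylate-forming enzyme, 11.1-fold lower in the authors' deposited table. Without the 10 members so matched, 15 of 30 were higher and 9 lower (adjusted p = 0.448 over the 10 added lists). Cell cycle and DNA replication had 25 of 66 lower, 23 higher and 18 not called (25 and 23 adjusted over the list alone; list adjusted p = 0.789). Its words also took in 14 RNA-directed DNA polymerases, as of retroelements, and 4 recycling genes, and without them 20 of 49 were higher and 17 lower (adjusted p = 0.921 over the 10 added lists). AN9500, a cyclin-related gene, fell 5.15-fold in the authors' deposited table. Autophagy had 8 higher, 8 lower and 6 not called of 22 (8 and 8 adjusted over the list alone; list adjusted p = 0.86). Of these, 4 members, 3 higher and 1 lower, matched only through vacuole fusion of the non-autophagic kind. Without them, 5 of 18 were higher and 7 lower (adjusted p = 0.766 over the 10 added lists). In edgeR, septation had 22 higher and 14 lower, cell cycle 24 and 29 and autophagy 8 and 9, and library totals moved these to 15 and 19, 13 and 42, and 5 and 14.

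Median, mean and test differed in sign for 4 lists. Autophagy had a median log2 change of 0.01, a mean of -0.02 and a test upward, and cell cycle a median of 0.04, a mean of -0.16 and a test downward. Oxidative stress had a median of 0.21, a mean of -0.02 and a test upward, and siderophore and iron a median of -0.27, a mean of 0.06 and a test downward.

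Marker and reference genes differed too. In the authors' deposited table, pyrG rose 1.41-fold and riboB 1.49-fold, while pyroA fell 2.12-fold, argB 2.89-fold and nkuA 3.36-fold. Strain markers thus had 2 higher and 3 lower of 5 (2 and 3 adjusted over the list alone; list adjusted p = 0.546). Of 4 reference genes, 3 were higher and 1 not called (3 adjusted over the list alone; list adjusted p = 0.147), with benA rising 1.51-fold, gpdA 1.24-fold and actA 1.21-fold in the authors' deposited table. Under library totals 3 of the 4 remained higher and 1 was lower.

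**Figure D2:**
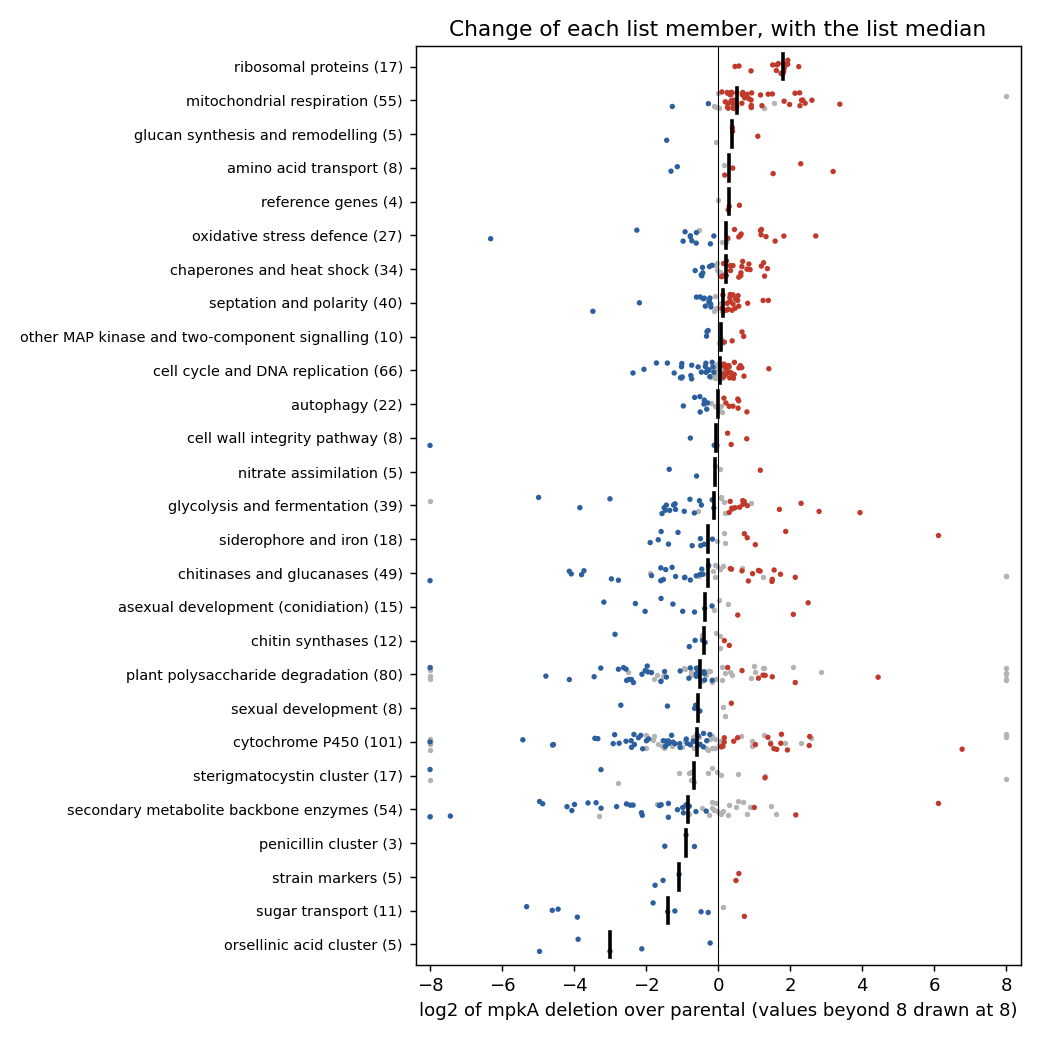
Log2 change, deletion over parental strain (x axis), of each tested member of the 27 lists (y axis, with the number tested), as points in red for called higher, blue for called lower and grey for not called; vertical bars are list medians. Values beyond 8, and genes at 0 reads in 1 strain, are drawn at 8 or -8. All 17 ribosomal protein genes lie above 0, and the orsellinic acid cluster has the lowest median at -3.00.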

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

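The fits on recovered reads, library totals, the set coefficients of variation and the length correction were chosen after seeing the data, as was the test of fry for either direction. A change of at least 2-fold left 2862 of the called genes, 958 higher and 1904 lower, by construction of the threshold. A coefficient of variation set to 0.2, where edgeR estimated 0.023, left 4095 genes, 1601 higher and 2494 lower, because a larger spread was assumed. The other settings gave between 6399 and 8164 genes. Leaving out 1 library gave 7669 to 7918 genes, with the lone library assumed to vary like the other strain's. mpkA kept its direction and its call in each fit. Of 117 named genes, 100 kept direction and call in every fit that tested them. The other 17 lost the call at a coefficient of 0.2, and 2 of them also at 0.1. Of the 5 lists called, 0 were called with an estimated correlation, 25 of 27 by fry and 27 by fry for either direction, which do not compare a list with other genes. Leaving out 1 library gave 5 to 7 lists.

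Among lists not called, 3 changed direction between tests of the same members, and the cause was not tested. Autophagy turned downward with camera on recovered reads (adjusted p = 0.992), a replicate block with a paired to b (0.994), an estimated correlation (0.995), library totals (0.715), without parental library a (0.898, where leaving out 1 library gave 0.864 to 0.984) and by fry (0.0699). Other kinase signalling turned downward under library totals (0.952), and septation by fry (0.101). With members left out, cell cycle (0.921) and the cell wall integrity pathway without mpkA (0.822) turned upward and autophagy downward (0.766). The recovered libraries carry no replicate number, so a replicate block was fitted under both possible pairings, chosen after seeing the data. It gave 8120 and 8072 genes and 6 lists each, and deviations correlated by -0.00695 and 0.00695. The pseudocounts and the filter on mean values set for a log test of deposited values were not run, since no such test was made, and the authors' single-strain tables do not compare replicates. Genes near the floor of 3 reads limit folds to bounds.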

Other observations

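The tests of explanations given here, and the genes named here, were all chosen after the result was seen. Some strongly changed genes lay side by side. Among 8776 expressed genes in genome order, 14 runs of at least 5 neighbours changed in the same direction on recovered reads. Each member changed by more than 1.5 on the log2 scale. Of the runs, 13 were lower and 1 higher, with 97 genes in all. For scale, edgeR called 2880 of 9338 genes changed by at least 2-fold, a looser cut than that of the runs. The higher run, AN7873 to AN7884, held 13 genes, among them fatty acid synthesis, aminotransferase and nonribosomal peptide synthetase genes, with a median change of 63.8-fold in the authors' deposited table. Lower runs included AN3225 to AN3231, with 7 genes around the polyketide synthase AN3230 (median 173-fold), and AN2030 to AN2038, with 9 genes and the polyketide synthases AN2032 and AN2035 (median 46.9-fold), in the authors' deposited table. A backbone enzyme, here a gene annotated as a polyketide or nonribosomal peptide synthase, stood in 5 of the 14 runs. Other classes of backbone enzyme were not searched for. Others held none, such as AN7592 to AN7597, with 7 genes including optB, annotated for tetrapeptide transport and 35.8-fold lower in the authors' deposited table, and AN7594, which fell from 257098 to 12323 normalized reads there, and AN1589 to AN1601, with 11 genes (median 7.33-fold).

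Chance order was argued against, since 97 genes stood in runs and the highest of 1000 shuffles within chromosomes gave 26 (permutation p = 0.001, the smallest they can give). Of 84 members of the lower runs, 74 (88.1%) had a 95% interval for the share of reads left above the interval of mpkA itself. This argues against their loss from the genome only if stray reads scale with the parental level. Among the 74 was the polyketide synthase AN3230, with 108 reads left (0.578%, 95% interval 0.474 to 0.698%). Others kept fewer reads than the 9 on mpkA, such as AN10384 (2 against 29) and AN10345 (2 against 79), and for these loss is not excluded. For the 10 not above the interval of mpkA, including AN8910, AN3227 and AN3199, loss cannot be told apart from a strong fall. Extra copies of the higher run, as the only cause, were argued against by folds from 4.64 to 110 among its members, a 23.6-fold range. Extra copies together with changed expression per copy would also give unequal folds and were not tested. A candidate explanation is that neighbouring genes are regulated together and differently between the strains, by the deletion or by another difference between them. It stays a hypothesis that no test here addressed directly, and 9 of the 14 runs held no backbone enzyme of the classes searched for. Whether the runs return when mpkA is restored would test it.

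The number of called genes was large and the spread between libraries small. A single library counted 2 times was argued against by the chi-square per degree of freedom, 1.54 in the strain with the lower value, where repeated draws give about 1. Library totals still gave 8063 genes, so the number did not hang on that choice of scaling, although the split moved. At the estimated coefficient of variation of 0.023, a shift of all genes could still leave most of them called. Whether scaling makes many of the small calls therefore cannot be told from the number. Whether separate cultures would vary more cannot be told apart from a true small spread, because the labels do not say which libraries share a culture. At an assumed coefficient of variation of 0.2, 4095 genes were called.

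The deletion libraries held a few mpkA reads, and the neighbouring gene model AN10731 (positions 2038007 to 2038452, plus strand, chosen after its values were seen), annotated with a protein kinase domain, lost its reads as well. Reads carried over from the parental libraries may account for what was left on mpkA, 0.0834% of the parental level. Of 2574 other genes deep enough for 0 reads to give a 95% interval below that share, 0 had one. To have one, a gene must also fall further than mpkA did. A count of 0 could therefore arise with or without reads carried over, and it does not decide between these. If reads were carried over, the folds of the 12 genes with over 1000 parental reads whose interval was not above that of mpkA, such as AN8910 (0.114%, 95% interval 0.0706 to 0.174%), would be lower bounds. AN10731 had 10 reads against 2669, which is 0.466% (95% interval 0.223 to 0.859%), above the interval of mpkA (0.0381 to 0.158%). That argues against loss of the whole gene only if stray reads scale with the parental level, as for the members of runs. The deleted mpkA itself kept 9 reads, against 13430. The model of AN10731 ends at 2038452, and mpkA starts at 2038483 on the same strand. Without reads by position, loss of all or part of AN10731 cannot be told apart from a fall in its expression. AN5667, on its other side, kept 125%. Beyond mpkA, AN5665, whose end overlaps it, had 20 reads against 69, AN5664 had 6 against 56 (13.3% left, 95% interval 4.70 to 30.9%), and AN5663 kept 90.8%.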
